A study of Homo sapiens with 6 samples.

How the data were processed

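The 6 libraries were made with a stranded TruSeq mRNA kit from TRIzol-extracted RNA, per the labels' protocols. The authors deposited FPKM values (fragments scaled by gene length and by library total) for 16070 genes, with symbols, NCBI gene IDs and GO and KEGG annotation. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and Cufflinks and the build GRCh38; their roles, versions, the annotation release and any filter on rows are not given in the sources used here. No further scaling was applied to the main values, and 0 columns of per-sample values were left unused. FPKM removes differences in gene length only if libraries share the same length dependence, which they did not here.

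Depth was recovered from the values themselves with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. In each library a gene's FPKM is a whole number of fragments times a step set by its length and the library total, and solving for these gave totals of 18553044, 18378477, 19192320, 19957335, 17665662 and 16775655 fragments for control replicates 1 to 3 and 6p replicates 1 to 3. The tolerance was 0.001 for the totals and much tighter for the gene lengths. All tested genes (100% of 11745) came out as whole fragments in every library, with a median gene length of 3904 nt. Listed genes held 99.6% of each total. Replicates of one group were compared on these fragments: chi-square per degree of freedom ran from 2.06 for 6p replicates 2 and 3 to 33.3 for 6p replicates 1 and 2, so every pair differed by more than sampling noise.

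Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; adjusted p-values of genes are from this test. A fold change on that scale understates the change of low genes. Group means are of 3 libraries with SD, and fold changes carry the moderated SE. The labels give the samples as independent, with nothing on whether they were separate cultures on separate days. The p-values of single genes therefore measure only the spread between these samples. Gene lists, 33 fixed before the data were examined, were tested with camera in limma at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. GO and KEGG terms of 10 to 500 tested genes were tested by one-sided hypergeometric tests of higher and of lower genes against tested genes with any term of that source (11535 and 4879 genes), adjusted within each source. Camera at the preset correlation and the term tests weigh genes against other genes, taken as nearly or fully independent. Their p-values therefore do not measure the spread between samples, and can be very small with 6 libraries. Ranges of adjusted p over settings cover the alternatives other than the estimated correlation and fry.

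Named genes followed a rule also fixed before the data were examined: the 8 largest log2 fold changes in each direction among changed genes with no overlap between groups, a mean of at least 1 FPKM in the higher group and a symbol that is not a clone, pseudogene, antisense or open reading frame name. To these were added up to 4 members of each list with the smallest adjusted p, or 2 with the highest mean where none passed, and 23 genes of lipid metabolism, stress and the cell cycle whatever their result. Genes named outside the rule are said to be so. Some genes under the rule, and 1 list, are not reported here. Coordinates are from GENCODE release 29 on GRCh38. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter and filters of 1 and 5 FPKM, median recentring, upper-quartile scaling, quantile normalization and rescaling to TPM. Others were eBayes without trend and robust, the replicate number as a block and leaving out each library in turn. Another 3 were added after the data were seen: removal of each library's loess trend (span 0.5) on log2 gene length, leaving out 2 libraries that stood apart by length, and limma voom on the recovered fragments. Counts were simulated for the comparison of 6p with control with 200 changed genes, not all of which passed the filter. About 11570 genes were tested. Of the changed genes tested, the test recovered 28.0% of those with a true log2 change of 0.32 and 85.7% at 0.58. It recovered 100% at 2-fold and at 4-fold, and called 10 of about 11370 unchanged genes. The simulated genes were independent, with a single dispersion (0.00656) and no length trend between libraries. These rates therefore do not carry over to the calls in the real libraries, which differed by length.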

Results

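RNA was sequenced from NCI-H1299, an established human non-small cell lung carcinoma line known to carry an NRAS mutation. The cells had been kept for 48 h with 25 µM of 6p or with vehicle (0.1% DMSO). The series describes 6p as a derivative of platensimycin, a Streptomyces natural product that inhibits a condensing enzyme of bacterial fatty acid synthesis. There were 3 control and 3 6p libraries, described as independent samples. One label field calls the controls untreated and the protocol gives them vehicle, and they are called control here. The fragment totals behind the values, recovered as described with the processing, were 18553044, 18378477 and 19192320 for control replicates 1 to 3. For 6p replicates 1 to 3 they were 19957335, 17665662 and 16775655. At such totals a single fragment in a gene of 2 kb is worth between 0.0251 and 0.0298 FPKM. The comparison asked which transcripts differ between cells given 6p and cells given vehicle.

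In 6p-treated cells, genes of the amino acid stress response rose most, while genes of mitosis and of cholesterol synthesis and uptake fell. DDIT4, an inhibitor of mTOR signalling, rose from 12.3 ± 0.880 to 221 ± 4.66 FPKM (mean ± SD, n = 3 in each group, as for all FPKM pairs that follow). Its log2 fold change was 4.06 ± 0.07 (SE, as for all fold changes that follow). TRIB3, a pseudokinase induced by amino acid shortage and endoplasmic reticulum stress, rose from 8.67 ± 0.869 to 116 ± 1.49 FPKM, and GDF15, a secreted stress cytokine, rose from 1.21 ± 0.185 to 23.9 ± 1.12 FPKM. MKI67, which encodes the proliferation marker Ki-67, fell from 41.0 ± 11.6 to 7.90 ± 2.03 FPKM, and SCD, the stearoyl-CoA desaturase, fell from 453 ± 53.3 to 113 ± 19.4 FPKM. Of 11745 genes tested, 5457 changed at adjusted p under 0.05 in limma, with 2506 higher and 2951 lower. Of these, 194 higher and 139 lower genes changed at least 2-fold on the log2(FPKM + 1) scale. The other leading higher genes were CHAC1, SESN2, UPP1, ASNS and DDIT3, with log2 fold changes of 3.29, 3.07, 3.15, 2.88 and 2.81. Other leading lower genes were FASN, KIF20A, CDKN2C and ANLN, at -1.90, -1.88, -1.87 and -1.77. Adjusted p in limma ran from 1.14e-07 for DDIT4 to 0.000263 for MKI67 among these genes. In GENCODE release 29 on GRCh38, DDIT4 (NCBI gene 54541) lies on chromosome 10, 72273920 to 72276036, and TRIB3 (57761) on chromosome 20, 362835 to 397559. SCD (6319) lies on chromosome 10, 100347124 to 100364834, FASN (2194) on chromosome 17, 82078333 to 82098332 and MKI67 (4288) on chromosome 10, 128096659 to 128126385.

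**Figure D1:**
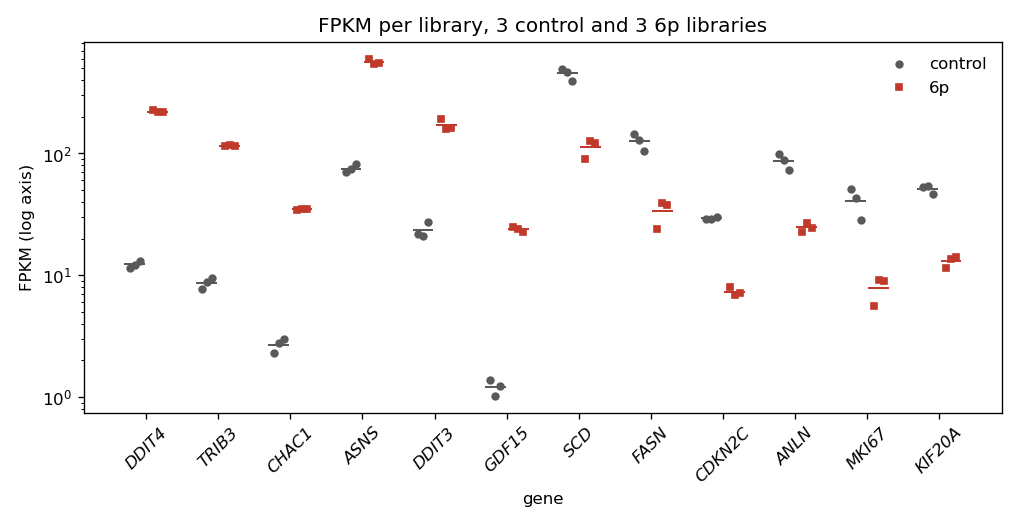
FPKM (log axis) of 12 genes in each library, with control libraries as grey circles, 6p libraries as red squares and each group's mean as a bar. The 3 6p libraries lie above the 3 control libraries for DDIT4, TRIB3, CHAC1, ASNS, DDIT3 and GDF15 and below them for SCD, FASN, CDKN2C, ANLN, MKI67 and KIF20A.

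Libraries differed by more than group. The first principal component took 79.9% of the variance and parted the groups, and the second took 13.0% and parted control replicate 3 and 6p replicate 1 from the other 4 libraries. In both of these libraries short genes read higher and long genes lower than in the rest of their group: Spearman's rho over genes between length and the difference from the group's other libraries was -0.677 for control replicate 3 and -0.517 for 6p replicate 1. The fold changes of 6p against control ran the same way, from a median of 0.25 in the shortest of 10 equal groups of genes to -0.22 in the longest. Genes are not independent replicates, so no p is attached. Without these 2 libraries, a choice made after the data were seen, 7742 genes changed, 3555 higher and 4187 lower. Control replicate 3 also lay toward the 6p libraries. Its median share of the way in FPKM from the other controls to 6p was 7.46% over 248 genes at least 2-fold higher and 30.6% over 197 genes at least 2-fold lower, picked without it.

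**Figure D2:**
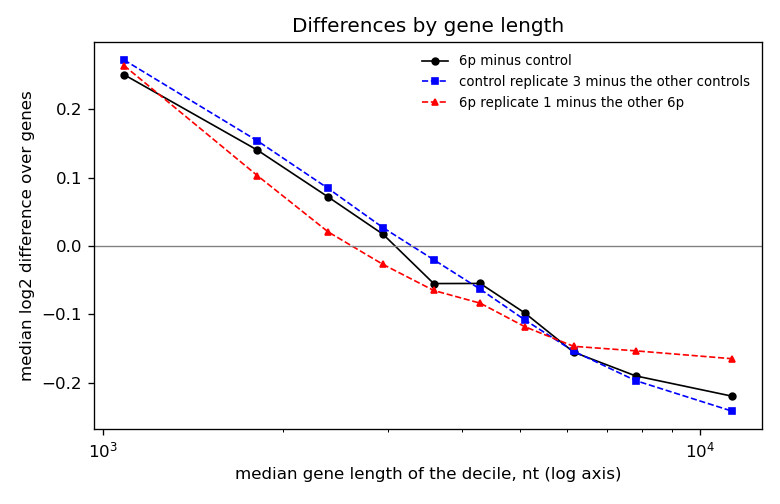
Median log2 difference over genes (vertical axis) against the median gene length in nt (log axis) of 10 equal groups of the tested genes, for 6p against control (black circles), control replicate 3 against the other controls (blue squares) and 6p replicate 1 against the other 6p libraries (red triangles). All 3 lines fall with length; that of 6p against control falls from 0.25 to -0.22.

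Genes of the ATF4 and amino acid stress response rose together. 30 of 34 tested members were higher and 2 lower (30 and 2 adjusted over the list alone), with a median log2 fold change of 1.48. ATF4, the transcription factor translated when eIF2α is phosphorylated, rose from 36.7 ± 3.29 to 76.0 ± 4.16 FPKM. Its known target DDIT3, which encodes the transcription factor CHOP, rose from 23.5 ± 3.54 to 171 ± 18.8 FPKM. ASNS, asparagine synthetase, rose from 75.2 ± 5.49 to 561 ± 28.7 FPKM, and CHAC1, a glutathione-degrading enzyme, from 2.69 ± 0.349 to 34.9 ± 0.429 FPKM. The 2 members that fell, named after their values were seen, were ATF5, at -0.90 ± 0.11, and ALDH18A1, a proline synthesis enzyme, at -0.48 ± 0.08. The list test passed at adjusted p = 2.01e-21, and at 0.0312 with an estimated correlation. Of endoplasmic reticulum chaperone and degradation genes, 7 of 29 were higher and 10 lower (8 and 10 adjusted over the list alone). The list test gave adjusted p = 0.656, which did not pass. HSPA5, which encodes the chaperone BiP, rose from 144 ± 8.0 to 233 ± 7.61 FPKM, XBP1 by 1.43 ± 0.09 and HERPUD1, a degradation factor, by 1.10 ± 0.08. Heat shock protein genes fell: 1 of 19 tested members were higher and 16 lower (1 and 17 adjusted over the list alone), with a median of -0.49 (adjusted p = 4.79e-06; adjusted p = 0.121 with an estimated correlation). HSPA1A went from 27.5 ± 1.89 to 14.1 ± 0.476 FPKM, CHORDC1 changed by -1.03 ± 0.08 and BAG3 by -0.69 ± 0.08. The 1 riser, named after its values were seen, was HSPB1 at 0.42 ± 0.14. HSPA1A has a near-identical copy, HSPA1B, and how shared reads were counted is not given in the sources used here.

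Cholesterol synthesis and uptake genes fell. 1 of 25 tested members were higher and 21 lower (1 and 21 adjusted over the list alone), with a median of -0.70 (adjusted p = 7.85e-09, and 0.0312 with an estimated correlation). HMGCS1, the HMG-CoA synthase, fell from 17.9 ± 0.211 to 7.25 ± 0.439 FPKM, and SQLE, the squalene epoxidase, from 49.0 ± 2.50 to 24.5 ± 0.720 FPKM. INSIG1, a sterol-regulated membrane protein, fell from 51.3 ± 2.76 to 17.6 ± 1.61 FPKM. The member that rose was TM7SF2, a sterol reductase, at 0.49 ± 0.08, named after its values were seen. In fatty acid synthesis, elongation and desaturation, 5 of 24 tested members were higher and 15 lower (5 and 15 adjusted over the list alone), with a median of -0.38. The list passed at adjusted p = 0.0172 (adjusted p = 0.504 with an estimated correlation), and not after rescaling to TPM (0.0561, range over settings 0.00145 to 0.0561). FASN, the fatty acid synthase, fell from 126 ± 19.4 to 33.7 ± 8.52 FPKM, and ACACA, which makes its malonyl-CoA substrate, from 14.0 ± 2.96 to 5.74 ± 1.72 FPKM. ACLY, which supplies cytosolic acetyl-CoA, fell from 57.3 ± 4.26 to 34.5 ± 5.94 FPKM, and SREBF1, which encodes the transcription factor SREBP1, from 77.0 ± 1.19 to 43.3 ± 4.90 FPKM. FADS3 and ME1 moved the other way, at 1.04 ± 0.08 and 0.80 ± 0.09. OXSM, the mitochondrial relative of the bacterial condensing enzymes, was 2.09 ± 0.427 FPKM in control and 2.57 ± 0.264 in 6p (log2 fold change 0.22 ± 0.12, adjusted p = 0.16).

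The 4 other lipid lists did not pass. For mitochondrial fatty acid synthesis and lipoylation, 4 of 10 were higher and 0 lower (4 and 0 adjusted over the list alone), at adjusted p = 0.0600 for the list. Lower members numbered 0 in limma at an unadjusted p under 0.05. The list passed without control replicate 3 (0.0279) or 6p replicate 3 (0.0460), and with a mean of at least 1 FPKM (0.0444, range over settings 0.0279 to 0.313). LIAS, the lipoyl synthase, changed by 0.47 ± 0.08. For fatty acid oxidation, 5 of 22 were higher and 2 lower (3 and 2 adjusted over the list alone). The list test gave adjusted p = 0.333. Its ECI1, an enoyl-CoA isomerase, rose from 51.1 ± 8.75 to 107 ± 14.6 FPKM. CPT1A, which starts mitochondrial import of fatty acids, was 13.5 ± 0.761 in control and 11.4 ± 1.27 FPKM in 6p (-0.23 ± 0.09, adjusted p = 0.0785, range over settings 0.0288 to 0.226). It passed as lower after rescaling to TPM (-0.41, adjusted p = 0.0452) and without the 2 libraries that stood apart by length (-0.17, adjusted p = 0.0288). For triglyceride synthesis, storage and lipolysis, 4 of 20 were higher and 5 lower (4 and 5 adjusted over the list alone), at adjusted p = 0.979 for the list. LPIN1, a phosphatidate phosphatase, fell from 16.2 ± 3.17 to 4.55 ± 1.51 FPKM, and PLIN2, which coats lipid droplets, was 32.6 ± 1.33 in control and 35.5 ± 1.08 FPKM in 6p (adjusted p = 0.173). For cholesterol efflux and LXR targets, 2 of 9 were higher and 4 lower (2 and 4 adjusted over the list alone). The list test gave adjusted p = 0.611. APOE, an apolipoprotein, rose from 20.4 ± 3.39 to 66.4 ± 12.8 FPKM. The median of the last 2 lists was 0.01 and 0.03, against means of -0.09 and -0.19.

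Genes of cell division fell. In mitosis, 0 of 59 tested members were higher and 56 lower (0 and 58 adjusted over the list alone), and higher members numbered 0 in limma at an unadjusted p under 0.05. The median was -0.98 (adjusted p = 3.14e-23, and 0.0312 with an estimated correlation). CCNB1, the mitotic cyclin B1, fell from 182 ± 14.3 to 96.8 ± 3.80 FPKM, and CCNA2, cyclin A2, from 71.4 ± 2.30 to 31.4 ± 0.865 FPKM. KIF20A, a cytokinesis kinesin, fell from 51.2 ± 4.44 to 13.2 ± 1.40 FPKM, and RACGAP1 changed by -1.11 ± 0.06. In DNA replication, 2 of 55 tested members were higher and 48 lower (2 and 49 adjusted over the list alone), with a median of -0.74 (adjusted p = 8.38e-16; adjusted p = 0.0549 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell from 111 ± 2.56 to 40.6 ± 2.17 FPKM. MCM10, a replication initiation factor, changed by -1.14 ± 0.07. The risers were CCND2, from 0.576 ± 0.0194 to 2.87 ± 0.318 FPKM, and CCNE1, at 0.48 ± 0.09, the latter named after its values were seen. CCND1, cyclin D1, was 111 ± 4.63 FPKM in control and 110.3 ± 10.6 in 6p (adjusted p = 0.877). In recombination and crosslink repair, 0 of 25 tested members were higher and 22 lower (1 and 23 adjusted over the list alone), and higher members numbered 1 in limma at an unadjusted p under 0.05. The median was -0.57 (adjusted p = 1.45e-07; adjusted p = 0.295 with an estimated correlation). RAD51AP1 changed by -0.86 ± 0.07 and BLM, a helicase, by -0.69 ± 0.08.

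Single genes of cell cycle arrest and cell death changed in both directions. CDKN1A, which encodes the CDK inhibitor p21, rose from 22.4 ± 0.662 to 46.0 ± 0.961 FPKM, and TNFRSF10B, a TRAIL receptor, from 16.9 ± 0.653 to 36.4 ± 3.81 FPKM. BBC3, which encodes PUMA, rose from 3.01 ± 0.243 to 6.92 ± 0.351 FPKM, and CDKN2C, which encodes the CDK inhibitor p18, fell from 29.3 ± 0.564 to 7.31 ± 0.560 FPKM. For apoptosis regulators, 9 of 30 were higher and 6 lower (9 and 6 adjusted over the list alone). The list test gave adjusted p = 0.453. The BH3-only genes HRK and PMAIP1 changed by 0.72 ± 0.07 and 0.81 ± 0.08. The members of this list named here all rose, and the 6 lower members are not among them. The list's median was -0.00 where its mean was 0.07.

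NRF2 targets and glutathione genes rose: 17 of 27 tested members were higher and 3 lower (18 and 4 adjusted over the list alone), with a median of 0.36 (adjusted p = 2.76e-05; adjusted p = 0.121 with an estimated correlation). HMOX1, heme oxygenase 1, rose from 17.3 ± 0.807 to 39.8 ± 1.29 FPKM, and NQO1, a quinone reductase, from 59.4 ± 5.89 to 124 ± 13.9 FPKM. SLC7A11, the cystine transporter, rose from 2.21 ± 0.408 to 8.32 ± 0.356 FPKM. The 3 lower members, named after their values were seen, were PGD, CBR3 and UGDH, at -0.43 ± 0.08, -0.61 ± 0.19 and -0.36 ± 0.07. In autophagy and lysosome, 17 of 40 tested members were higher and 3 lower (17 and 3 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00115; adjusted p = 0.121 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose from 234 ± 13.4 to 482 ± 19.5 FPKM, and MAP1LC3B, which encodes the autophagosome protein LC3B, from 69.9 ± 2.25 to 123 ± 9.57 FPKM. LAMP3, a lysosomal membrane protein, rose from 0.893 ± 0.0709 to 5.45 ± 0.386 FPKM, while GLA, ATP6V0D1 and ATP6V1A, named after their values were seen, changed by -0.30 ± 0.07, -0.26 ± 0.08 and -0.50 ± 0.07. For iron handling and ferroptosis, 9 of 24 were higher and 9 lower (9 and 10 adjusted over the list alone). The list test gave adjusted p = 0.656, and its median of -0.11 differed in sign from the mean of 0.18. FTH1 and FTL, the ferritin subunits, rose by 1.24 ± 0.12 and 1.24 ± 0.12, and by 1.00 and 0.94 with the length trend removed. Both have processed pseudogenes, which could share their reads. GPX4, the lipid hydroperoxide reductase, went from 209 ± 33.6 to 279 ± 35.6 FPKM (adjusted p = 0.0390, range over settings 7.19e-06 to 0.13). That call was lost without control replicate 1 (0.13), control replicate 2 (0.128), 6p replicate 1 (0.0968) or 6p replicate 3 (0.0805). The log2 fold change of GPX4 went from 0.42 to 0.16 with the length trend removed (adjusted p = 0.0357 in limma). In the xenobiotic response, 6 of 9 tested members were higher and 1 lower (6 and 1 adjusted over the list alone), at adjusted p = 0.0401 (adjusted p = 0.25 with an estimated correlation). This was lost without control replicate 3 (0.0537) or 6p replicate 2 (0.0558) and with the length trend removed (0.0746, range over settings 0.0175 to 0.154). CYP1B1, a cytochrome P450, changed by 0.61 ± 0.09. For metallothioneins and zinc, 2 of 5 were higher and 1 lower (2 and 1 adjusted over the list alone), at adjusted p = 0.611 for the list. MT2A, of a family of close copies, changed by 0.78 ± 0.14. With the length trend removed its change was 0.36 (adjusted p = 0.000107 in limma).

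Transcripts of cytosolic ribosomal proteins read higher: 74 of 78 tested members were higher and 1 lower (74 and 1 adjusted over the list alone), with a median of 0.65 (adjusted p = 6.07e-15; adjusted p = 0.522 with an estimated correlation). RPL12 went from 1514 ± 207 to 3205 ± 260.1 FPKM and RPS27 from 720.5 ± 111 to 1372 ± 223 FPKM. The 1 lower member, named after its values were seen, was RPS10 at -0.56 ± 0.11. Ribosomal protein genes have processed pseudogenes, so their values are uncertain where shared reads were split. These genes are short, with a median length of 1105 nt against 3904 nt for all tested genes, and the list median was 0.43 once the length trend was removed (71 of 78 higher, adjusted p = 2.72e-16, and 0.330 with an estimated correlation). The nuclear-encoded respiratory chain, with a median length of 1278 nt, had 14 of 76 members higher and 0 lower (1 and 0 adjusted over the list alone). Lower members numbered 3 in limma at an unadjusted p under 0.05. The list had a median of 0.21 and adjusted p = 0.00733 (adjusted p = 0.723 with an estimated correlation). That call was lost without control replicate 1 (median 0.125, adjusted p = 0.0832) or 6p replicate 1 (median 0.072, adjusted p = 0.354). With the length trend removed the median was -0.030, with 11 members higher and 21 lower (adjusted p = 0.448, range over settings 1.88e-05 to 0.448). Of the 13 mitochondrially encoded members, 0 were among the genes used here. In ribosome biogenesis, 2 of 44 tested members were higher and 21 lower (2 and 22 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.0106; adjusted p = 0.266 with an estimated correlation). The call was lost without control replicate 3 (0.0540, range over settings 2.56e-05 to 0.0540). UTP20, a ribosomal RNA processing factor, fell from 10.3 ± 1.90 to 3.92 ± 0.665 FPKM, and ODC1, ornithine decarboxylase, rose by 0.51 ± 0.09. MYC was 39.4 ± 1.49 FPKM in control and 42.2 ± 3.64 in 6p (adjusted p = 0.386, range over settings 0.0197 to 0.689). It passed as higher with the length trend removed (0.16, adjusted p = 0.0347) and without the 2 libraries that stood apart by length (0.14, adjusted p = 0.0197).

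NF-kB and inflammatory cytokine genes rose: 17 of 20 tested members were higher and 1 lower (17 and 2 adjusted over the list alone), with a median of 0.64 (adjusted p = 3.59e-07, and 0.0320 with an estimated correlation). CXCL2, a chemokine, rose from 74.6 ± 14.2 to 345 ± 58.7 FPKM, RELB, an NF-kB subunit, from 45.4 ± 4.03 to 96.3 ± 2.37 FPKM, and IL32 from 25.2 ± 2.87 to 67.8 ± 6.57 FPKM. SOD2, mitochondrial superoxide dismutase, named after its values were seen, fell by 0.34. In MAPK pathway output, 10 of 23 tested members were higher and 3 lower (10 and 3 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.0293; adjusted p = 0.522 with an estimated correlation). It was lost without control replicate 3 (0.0668, range over settings 0.00888 to 0.0668). After rescaling to TPM the median was -0.08. Its IER3, JUNB and DUSP6 changed by 1.10 ± 0.09, 1.03 ± 0.07 and 0.88 ± 0.08. In the interferon list, 6 of 27 were higher and 5 lower (6 and 5 adjusted over the list alone). The list test gave adjusted p = 0.438, and 0.0485 with a mean of at least 5 FPKM (range over settings 0.0485 to 0.910). OAS3, an antiviral synthetase, fell from 6.19 ± 1.08 to 2.07 ± 0.426 FPKM. UBE2L6, IFIT2 and IRF7 rose by 0.78 ± 0.10, 0.69 ± 0.09 and 0.44 ± 0.09, and the call of IRF7 was lost after rescaling to TPM (0.0685). For YAP/TAZ and TGF-beta targets, 7 of 26 were higher and 10 lower (7 and 11 adjusted over the list alone), at adjusted p = 0.652 for the list. TGFB2, a TGF-beta ligand, went from 3.31 ± 0.617 to 0.919 ± 0.190 FPKM and ANKRD1, a nuclear ankyrin repeat protein, from 16.0 ± 1.62 to 8.65 ± 0.319 FPKM.

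For the mesenchymal and matrix list, 12 of 31 were higher and 4 lower (12 and 4 adjusted over the list alone), at adjusted p = 0.0936 for the list. It passed without control replicate 1 (0.0474) or 6p replicate 1 (0.0383), and with a mean of at least 1 FPKM (0.0444, range over settings 0.0383 to 0.230). It also passed after rescaling to TPM (0.0438), where its median turned from 0.08 to -0.10. MMP1, a collagenase, rose from 1.42 ± 0.225 to 7.07 ± 0.543 FPKM and COL6A2 by 0.86 ± 0.07. For epithelial markers, 4 of 10 were higher and 0 lower (4 and 0 adjusted over the list alone), at adjusted p = 0.0936 for the list, and lower members numbered 0 in limma at an unadjusted p under 0.05. The list passed with a mean of at least 1 FPKM (0.0359) and after rescaling to TPM (0.0484, range over settings 0.0359 to 0.347). CLDN1, a tight junction claudin, rose from 11.0 ± 0.714 to 35.9 ± 1.13 FPKM. Neuroendocrine and neuronal markers passed at adjusted p = 0.0400 (adjusted p = 0.465 with an estimated correlation): 4 of 8 tested members were higher and 1 lower (4 and 1 adjusted over the list alone). UCHL1 went from 573 ± 64.5 to 1024 ± 131 FPKM and CHGB, chromogranin B, from 2.60 ± 0.172 to 7.31 ± 0.931 FPKM. The list's call was lost without control replicate 1 (0.0710) or 6p replicate 3 (0.0531) and with the length trend removed (0.128, range over settings 0.0252 to 0.358). For glycolysis and hypoxia targets, 7 of 32 were higher and 9 lower (7 and 9 adjusted over the list alone), at adjusted p = 0.670 for the list. VEGFA, the angiogenic growth factor, rose from 8.43 ± 0.367 to 36.2 ± 2.30 FPKM and LDHA, lactate dehydrogenase A, fell from 254 ± 6.44 to 139 ± 2.13 FPKM. Of 21 blood cell markers, 3 were tested, too few for a list test. Of these 0 were higher and 1, ITGAM, was lower at -0.33 ± 0.08 (adjusted p = 0.0131, 0.0584 without control replicate 2, range over settings 0.00350 to 0.0584). The highest was CD68 at a mean of 62.1 FPKM over the 6 libraries. Of 17 fibroblast and endothelial markers 0 were tested, and the highest, ERG, had a mean of 0.316 FPKM.

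**Figure D3:**
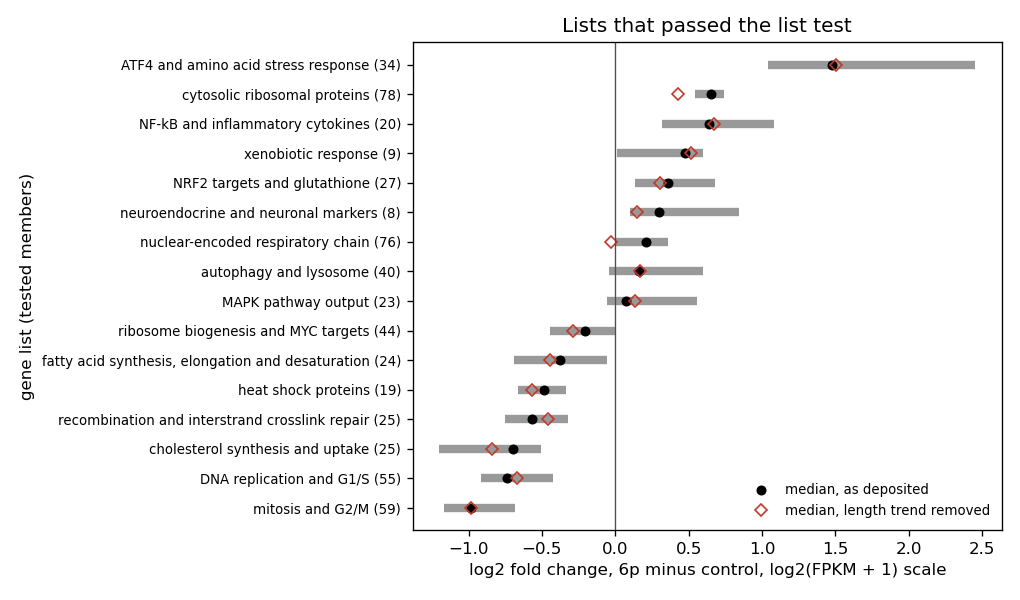
Median log2 fold change of the 16 gene lists that passed the list test, on the log2(FPKM + 1) scale (horizontal axis), with the number of tested members beside each name; black circles are the values as deposited, grey bars the interquartile range over members, and red diamonds the medians with the length trend removed. The ATF4 list stands at 1.48 and mitosis at -0.98, and the respiratory chain moves from 0.21 to -0.03.

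Annotation terms were tested beside the lists, with one-sided hypergeometric tests. Among lower genes, KEGG's cell cycle pathway had 71 of 119 tested genes (adjusted p = 3.08e-12), DNA replication 26 of 35 (7.10e-07) and the Fanconi anemia pathway 28 of 52 (0.00304). Steroid biosynthesis had 12 of 18 (0.0225), and missed the threshold with the length trend removed (0.0540). The 4 KEGG terms among higher genes were the ribosome with 80 of 126 genes (1.90e-22), a coronavirus disease pathway with 85 of 146 (1.54e-20), glutathione metabolism with 18 of 36 (0.0121) and ferroptosis with 16 of 33 (0.0225). Among lower genes 16 KEGG terms were enriched, of 301 tested. GO gave 29 terms among higher and 141 among lower genes, of 2896 tested. Cell division had the smallest p of the lower GO terms, with 163 of 327 genes (adjusted p = 2.66e-19).

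Of 30 lists tested, 9 passed as higher and 7 as lower with a preset correlation, and with an estimated correlation the ATF4, mitosis, cholesterol and NF-kB lists held. A call lost there need not mean that members were correlated, because that setting also rests on the few degrees of freedom of the 6 libraries. The xenobiotic list had an estimated correlation of -0.019, below the preset 0.01, yet its adjusted p in camera went from 0.0401 to 0.25. The count of changed genes fell from 5457 to 3517 without control replicate 2. Rescaling to TPM moved the share of higher genes among those changed from 45.9% to 27.7% and the median log2 fold change of all genes from -0.04 to -0.21. Recentring each library on its median ratio gave 2787 higher and 2686 lower genes, so which direction held more genes depended on the scaling.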

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

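The removal of the length trend, the omission of the 2 libraries that stood apart by length and voom were chosen after the data were seen. Of 133 tested named genes, 118 stayed on one side of the threshold under every alternative that tested them, with one direction where they passed it, and 117 of these kept the sign of their fold change throughout. Of 30 lists, 20 stayed on one side in the same way, estimated correlation and fry set aside, and 13 of these kept the sign of their median. No gene was called in opposite directions by any setting and the reported test. The 2-fold counts depended on the pseudocount, because a larger one shrinks low genes. From 194 higher and 139 lower they went to 403 and 282 at 0.1, 448 and 318 at 0.01, and 449 and 321 with voom, which called 5399 genes in all. Requiring 2-fold as well left 333 genes and 81 terms in place of 190. Rescaling to TPM lowers log2 ratios because FPKM summed to more in 6p. It also raises all values against an unchanged pseudocount, since FPKM summed to only 362369 to 459212 per library. It gave 1526 higher genes and 403 at least 2-fold lower, and there the fatty acid synthesis list missed the threshold (adjusted p = 0.0561). How much each of these adds to the 2-fold count was not tested. Leaving out 1 library gave 3517 to 6084 changed genes, 1724 to 2706 higher and 1793 to 3378 lower, lowest without control replicate 2 and highest without control replicate 3. From 183 to 248 genes were at least 2-fold higher and 114 to 197 lower, 14 to 16 lists passed and 172 to 206 terms were enriched. The number of lists was 4 with an estimated correlation and 25 with fry, which asks a different question. With the length trend removed, 6267 genes changed, 4757 of them shared in direction with the 5457, and the respiratory chain list turned from 0.21 to -0.030 (adjusted p = 0.448). The MAPK, neuroendocrine and xenobiotic lists also lost their calls with no filter on low values (0.0650, 0.0524 and 0.154). With a mean of at least 5 FPKM the neuroendocrine (0.358) and xenobiotic (0.0576) lists did so, and with median recentring the xenobiotic list (0.0502). The causes were not tested beyond what is said here.

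Replicate numbers did not pair the libraries: deviations from group means correlated at -0.594, 0.359 and -0.433 for numbers 1, 2 and 3 over 2000 variable genes, and not every library correlated best with its own number. With the number as a block, 3694 genes changed, 1774 higher and 1920 lower, with fewer degrees of freedom. A count model was planned only for whole counts and was not run on FPKM. On simulated counts at the real totals, made without a length trend between libraries, 28.0% of genes with the smallest simulated change were recovered. How recovery depends on depth or on expression level was not tested.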

Other observations

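Among genes lower in 6p-treated cells, annotation terms of the nuclear pore and of mRNA splicing, outside the lists fixed beforehand, were enriched. The genes named here were chosen after their values were seen. Among lower genes were 18 of 24 tested genes annotated as structural constituents of the nuclear pore (adjusted p = 6.56e-05, one-sided hypergeometric test) and 94 of 244 of mRNA splicing (0.000279), so most tested splicing genes were not called lower. NUP153, a basket nucleoporin, went from 45.5 ± 8.68 to 21.9 ± 2.68 FPKM, NUP62, a central channel nucleoporin, changed by -0.69 ± 0.11 and NDC1, a membrane nucleoporin, by -0.87 ± 0.08. The splicing factors SRSF1 and HNRNPM changed by -0.71 ± 0.07 and -0.88 ± 0.09, while PLRG1 rose by 0.64 ± 0.07. Among higher genes were 12 of 19 genes of collagen breakdown (0.00541) and 24 of 45 serine-type endopeptidases (0.000233), with MMP9, a gelatinase, from 1.10 ± 0.0835 to 3.83 ± 0.134 FPKM and LONP1, the mitochondrial protease, from 37.4 ± 0.442 to 68.9 ± 5.25 FPKM. PRSS23, a secreted serine protease, fell from 28.4 ± 0.577 to 13.1 ± 0.984 FPKM.

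All tests of explanations in the paragraphs that follow were chosen after the result was seen. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 5457 genes, and the highest of the other splits 0 in limma, where the largest count at an unadjusted p under 0.05 was 690 against 6417. For lists the real split gave 16 and the highest other 12, and for terms 190 and 0. In each case 1 of the 10 splits, the real one, gave as many. Every other split puts libraries of both groups on each side, so the difference between the groups widens its spread. The counts of 0 for genes and terms there are therefore no measure of what chance would give.

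Fold changes fell with gene length, and a length bias that differs between libraries whatever their group is a candidate explanation for part of that: the trend also ran within groups, at rho = -0.677 for control replicate 3 and -0.517 for 6p replicate 1. Length as the whole cause of the shift is argued against for the ATF4, mitosis and cholesterol lists, and less firmly for ribosomal proteins. Their medians with the trend removed were 1.5 for ATF4, -0.98 for mitosis, -0.84 for cholesterol and 0.43 for ribosomal proteins. Each was past the list test at the preset correlation, with quartiles on one side of 0, and so was the 95% t interval of the difference in list median between the 3 and 3 libraries, 1.43 to 1.56, -1.03 to -0.92, -0.97 to -0.72 and 0.20 to 0.60. With an estimated correlation the first 3 passed with the trend removed (adjusted p = 0.0206, 0.0206 and 0.0294). The ribosomal proteins passed neither before (0.522) nor after (0.330), so that test does not bear on length. Removal used the gene lengths behind the FPKM values, such as 7573 nt for RPL37. Yet RPL37 followed short genes, at 109 FPKM in control replicate 3 against 85.5 and 93.0 in the other controls. Removal raised RPL37 from 0.82 to 0.99 and RPL28 from 0.86 to 0.96, and lowered RPL12 from 1.09 to 0.73 and RPS27 from 0.93 to 0.53. It may therefore leave length bias in some members. For the respiratory chain the trend may account for the shift. Its median went from 0.21 (quartiles 0.00 and 0.36) to -0.030 (quartiles -0.20 and 0.12), and the call ended because the median fell to about 0. Single members were still called with the trend removed, 11 higher and 21 lower, against 14 and 0 before. Whether 6p itself acts differently on long and short transcripts cannot be told apart from library bias here, since the exact two-sided permutation p of the 3 against 3 slopes on length was 0.1, the smallest that design can give.

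Control replicate 3 lay toward the 6p libraries on many lower genes. RNA of 6p-treated cells mixed into it would move every gene by one share of FPKM. As deposited, the median share of the way from the other controls to 6p was 7.46% over 248 genes at least 2-fold higher and 30.6% over 197 at least 2-fold lower, picked without that library. The lower share exceeded the higher by 23.1 points. The other 5 libraries, each left out the same way, gave differences of -6.99 to 0.429 points and t bounds for a further library of -20.8 to 13.5, adjusted for 6 libraries. The 23.1 points lay outside those bounds. In the other controls, too, the lower share lay farther from 0 than the higher. It was -8.62% against -1.87% for control replicate 1 and -4.48% against -1.03% for control replicate 2. The bounds pool control and 6p libraries, so they may be too narrow for a control. The difference between the shares therefore cannot decide whether a mixture alone was at work. With the length trend removed the shares were 3.25% over 173 and 16.0% over 158 genes. That difference, 12.8 points, lay within its bounds (-19.9 to 15.6), so a mixture beside length bias cannot be told apart from variation between libraries. The 16.0% of the lower genes also lay within the bounds from the other libraries (-24.6 to 23.1), which gave -6.90 to 3.69%, so length bias alone stays open too. With 5 libraries, which share their references, these bounds are wide. A difference in the state of that culture, such as its growth, may contribute and was not tested.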
